A study of Rattus norvegicus with 8 samples.

How the data were processed

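Total RNA from penile tissue of 8 rat samples, 4 labelled Control and 4 labelled Model, was treated with RNase R, amplified by random priming, labelled with Cy3 and hybridised to 1-colour circRNA arrays, per the labels' protocols. Per the labels, 1 μg of labelled cRNA was hybridised for 17 h at 65 °C. Groups and replicate numbers were taken from the sample titles.

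Per the file headers, the arrays were read with Agilent Feature Extraction 11.0.1.1, whose processed signal is the intensity of a spot after background subtraction and spatial detrending. The deposited files also give the median intensity of each spot and of its local background, and flags for spots that are saturated, not uniform or well above background. No scaling between arrays is recorded in them. The authors also deposited a table of log2 values for the circRNA probes. How that table was normalized is not given in the sources used here. Its columns have medians of 5.61 to 5.63 and nearly the same distribution, and each ranks the probes like the processed signal of its array (Spearman's rho 0.993 to 0.999 across probes, which are not independent replicates). Whether a background was subtracted from the table stays unknown. It was used as an alternative.

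Each array has 15165 spots that are not controls, for 14227 probes. Of these, 14145 are circRNA probes, 62 are probes whose file entry is an mRNA accession, with 10 spots each, and 20 are custom probes with no accession. Gene symbols came from the RefSeq gene table of the rat assembly GRCr8 by accession without version, and 39 of the 62 mRNA probes matched. Spots flagged as not uniform were left out, and 56 circRNA probes with no value on some array for that reason were not tested. The spots of a probe were averaged on the log2 scale. The median coefficient of variation over the 10 spots of an mRNA probe was 5.50% to 9.51% per array.

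The main values are log2 of the processed signal minus the array's 75th percentile over all probes that are not controls. Probes well above background on at least 4 of the 8 arrays were kept. Model was compared with Control in limma 3.58.1 under R 4.3.3 (lmFit and eBayes), with Benjamini-Hochberg adjustment over circRNA and mRNA probes together and a threshold of 0.05. Fold changes are on this relative scale, so a shift shared by most probes is not visible. Array measures were compared by exact two-sided permutation over 70 splits, whose smallest p is 0.0286. Data were simulated for the comparison of Model with Control over 13646 probes. At each fold, 50 probes were changed, with independent noise and no run effect. The fit recovered 2% of those changed 1.5-fold, 20% at 2-fold, 76% at 3-fold and 88% at 4-fold, and 4 of 97 calls were false. In the data 47.2% of the circRNAs passed, so the cut on unadjusted p is looser there and these rates do not carry over.

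The test, the filter, the rule for naming circRNAs and most alternatives for the circRNAs were fixed before the data were examined; normexp on the median intensity, the comparisons without Control replicates 3 and 4 and against Control 1 alone, and all alternatives for the mRNA probes were added afterwards. The rule called for the 12 largest rises and the 12 largest falls among changed circRNAs whose groups do not overlap. Since the files do not pair the probes with names, 2 of each are given. The mRNA panel was found in the files and lay outside that rule: its changed genes with a symbol, all its custom probes with a symbol and 4 further genes were named after their values were seen. The planned results for the circRNA of the title, for Rhoa and for the 15 host gene lists, which cover smooth muscle contraction, RhoA and ROCK signalling, nitric oxide and cyclic nucleotides, extracellular matrix, TGF-beta, insulin, oxidative stress, mitochondria, endothelium, skeletal muscle, epithelium, nerve, immune cells, adipocytes and hosts of well described circRNAs, were not obtained.

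The alternatives were quantile normalization, median centring, the 75th percentile over probes well above background on all 8 arrays, normexp background correction (offset 50) on the median intensity, other filters on dim probes, eBayes with trend and robust, the replicate number as a block, the scanning run as a random block, the deposited log2 table, and leaving out arrays. Array precision depends on signal over background: the median local background was 12.5 to 15 intensity units and the 75th percentile of the processed signal 47.9 to 127.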

Results

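Circular RNAs were measured in penile tissue of rats in 4 samples labelled Control and 4 labelled Model. The title of the series names diabetes-induced erectile dysfunction, and the labels describe the test that assigned it. Rats received 100 μg/kg of apomorphine, a dopamine agonist that elicits erection, and were watched for 30 min. The labels do not say that Model stands for this condition, which is inferred from the title and that test. Circular RNAs (circRNAs) are RNA loops made by back-splicing. RNase R, which degrades linear RNA, was used to enrich them before labelling. Each sample was hybridised to 1 array with 14145 circRNA probes and 62 probes for mRNAs. Nothing in the labels says that each sample came from a separate animal, so the p-values below measure the spread between these samples, which may be partly technical. The number of arrays, 4 per group, limits the precision of every value.

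All arrays gave usable signal. Between 91.8% and 97.9% of the circRNA probes were well above background on an array, and no spot was saturated. Before normalization, the 75th percentile of the log2 signal was 6.32 ± 0.60 in Control and 6.05 ± 0.23 in Model (SD, n = 4), a difference within the spread between arrays (exact two-sided permutation test, p = 0.429, adjusted p = 0.571 over 8 array measures). The share of circRNA probes well above background was 95.8% ± 2.56 in Control and 93.2% ± 1.47 in Model (SD, n = 4; exact permutation p = 0.143, adjusted p = 0.229). The brightest probes stood further out in Model: the 99th percentile lay 6.10 ± 0.13 above the 75th percentile on the log2 scale, against 4.68 ± 0.77 in Control (SD, n = 4; exact permutation p = 0.0286, the smallest that 4 against 4 allows, adjusted p = 0.0762). The 100 brightest circRNA probes took 28.6% to 72.9% of the summed circRNA signal on the Control arrays and 36.9% to 43.8% on the Model arrays.

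**Figure D1:**
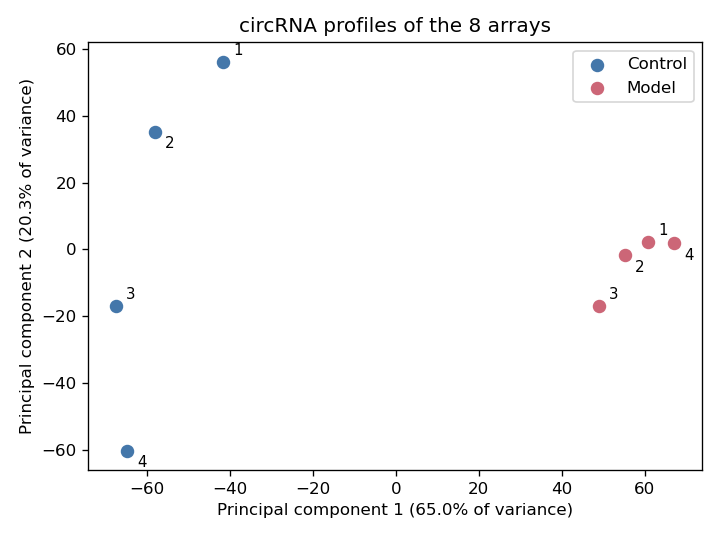
Principal components of the normalized log2 signal of the tested circRNAs on the 8 arrays, with each point 1 array numbered by its replicate. The horizontal axis (65.0% of the variance) separates the 4 Model arrays from the 4 Control arrays, and the vertical axis (20.3%) spreads the Control arrays. By Spearman's rho, Control 1 was closer to Control 2 and 3 (0.953 and 0.899) than to the Model arrays (0.848 to 0.877). It was further from Control 4 (0.834) than from any Model array.

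The question for the circRNAs was which of them differ between Model and Control tissue. The circRNA ASCRPR008579, whose groups did not overlap, fell from 5.61 ± 1.12 in Control to -0.03 ± 1.24 in Model (log2 signal relative to the array's 75th percentile, SD, n = 4), a fall of 49.9-fold. ASCRPR007908 fell 41.2-fold, from 4.11 ± 0.75 to -1.26 ± 1.43, and its value in Model 2 was 0.88 against -2.05 to -1.89 in the other Model arrays. ASCRPR005854 rose 21.9-fold, from -0.41 ± 0.80 to 4.04 ± 0.42, and ASCRPR005477 rose 14.6-fold, from -0.42 ± 0.48 to 3.44 ± 0.28. These 4 probes are given by the array's own identifiers, since the files do not pair them with host genes. They are the 2 largest falls and the 2 largest rises among changed circRNAs whose groups do not overlap. Their folds may thus be overstated, and passing the alternatives below on the same arrays adds little support. Each has 1 spot per array.

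The log2 changes of ASCRPR008579 and ASCRPR007908 were -5.64 (SE 0.65) and -5.36 (SE 0.63), with limma adjusted p of 1.11e-04 and 1.24e-04. Those of ASCRPR005854 and ASCRPR005477 were 4.45 (SE 0.38) and 3.87 (SE 0.26), with limma adjusted p of 2.86e-05 and 1.48e-05. All 4 passed in each of 20 alternatives, with log2 changes of -6.32 (quantile normalization) to -3.99 (against Control 1 alone) for ASCRPR008579, -6.08 (without Model replicate 2) to -3.85 (normexp) for ASCRPR007908, 3.48 (normexp) to 4.77 (median centring) for ASCRPR005854 and 2.95 (normexp) to 4.19 (median centring) for ASCRPR005477.

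Changes of this kind were widespread. Of 13585 circRNAs tested with limma, 6406 changed at an adjusted p under 0.05, or 47.2%, of which 3009 were higher and 3397 lower in Model. At 2-fold or more, 1815 were higher and 1984 lower, and at 4-fold or more 354 were higher and 314 lower. The groups did not overlap for 5849 circRNAs, or 43.1%, where chance gives 2.86%. In detection, 90 circRNAs were well above background on all 4 Control arrays and on no Model array, against 2 with the opposite pattern; detection is judged on unscaled signal, whose median on the log2 scale was 5.13 ± 0.58 in Control and 4.54 ± 0.18 in Model (SD, n = 4; exact permutation p = 0.114, adjusted p = 0.229).

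Direction went with brightness. Among the brightest 10% of the circRNAs, 926 were higher and 35 lower in Model, with a median log2 change of 1.25. Among the dimmest 10%, 111 were higher and 307 lower, with a median of -0.15. After quantile normalization the median log2 change of the brightest 10% was 0.19.

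The balance of higher and lower circRNAs depended on the zero point and the normalization. The share of higher calls was 47.0% here, 68.3% with arrays centred on their medians (4684 higher and 2174 lower, the median circRNA moving from -0.03 to 0.29) and 38.4% with the percentile over probes detected on all arrays (2502 and 4015, the median circRNA at -0.16). With normexp, which also changes the signal column and the background correction and adds an offset, it was 61.8% (2198 and 1357). Control 1 was scanned in a run of its own, Control 2 to 4 in another and the 4 Model arrays in yet another, so no run held both groups. With run as a random block, 4042 circRNAs changed. The 2364 calls that ended had a median log2 change 0.977 times that without the block and a median SE 1.36 times as large. The block reweights the Control arrays and widens the errors. It cannot remove a difference between the Model run and the Control runs.

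**Figure D2:**
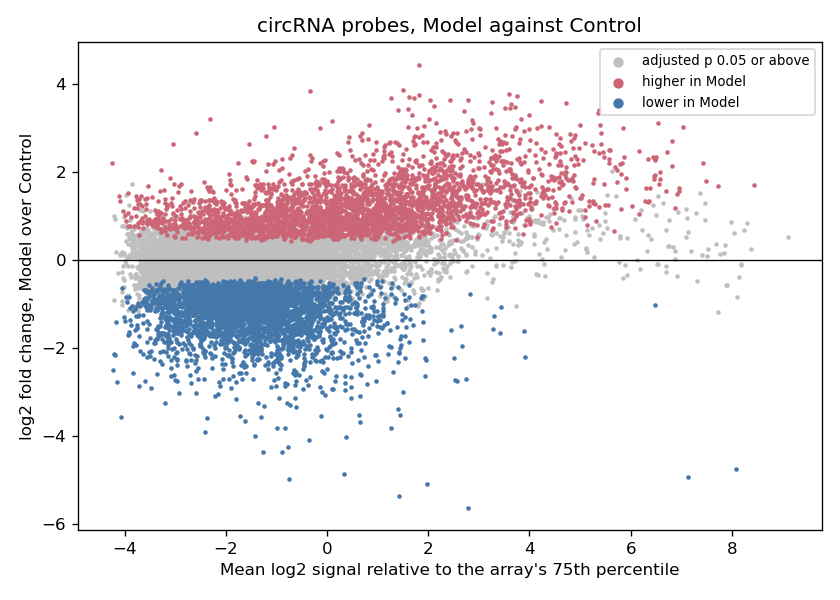
Log2 fold change of each tested circRNA, Model over Control, against its mean log2 signal relative to the array's 75th percentile. Coloured points are the 3009 circRNAs higher and the 3397 lower in Model at a limma adjusted p under 0.05, with the higher ones gathered at bright signal.

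The array also carries probes for mRNAs, each on 10 spots. RNase R had degraded linear RNA before labelling, so these probes read RNA left after digestion. Their changes need not follow mRNA levels in the tissue. Pdcd10, whose product belongs to the cerebral cavernous malformation protein complex of endothelial cells, fell 3.80-fold in Model, from 0.18 ± 0.34 to -1.75 ± 0.26 (log2 signal relative to the array's 75th percentile, SD, n = 4). Slc28a2, a sodium-coupled nucleoside transporter, fell 3.75-fold, from -0.62 ± 0.18 to -2.53 ± 0.23. P2rx2, an ATP-gated cation channel, fell 2.43-fold, from 0.34 ± 0.37 to -0.94 ± 0.27. Ldha, the lactate dehydrogenase subunit that favours lactate production, fell on both of its probes, by 2.59-fold and 1.67-fold. Hsp90ab1, a cytosolic chaperone, rose 2.29-fold, from 4.87 ± 0.11 to 6.06 ± 0.04, but had a log2 change of -0.33 under quantile normalization.

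Of 61 mRNA probes tested, 28 changed at a limma adjusted p under 0.05, with 9 higher and 19 lower in Model, and 28 also passed when adjusted over the panel alone. They include 16 genes with a symbol, 4 higher and 12 lower. The log2 changes of Pdcd10, Slc28a2 and P2rx2 were -1.93 (SE 0.22), -1.91 (SE 0.19) and -1.28 (SE 0.23), with limma adjusted p of 1.11e-04, 4.85e-05 and 0.00135. The Ldha probes gave -1.37 (SE 0.18) and -0.74 (SE 0.17), with limma adjusted p of 2.10e-04 and 0.00580. Hsp90ab1 gave 1.19 (SE 0.16), with a limma adjusted p of 2.29e-04. With normexp, which compresses dim signals, the log2 changes of Pdcd10, Slc28a2 and P2rx2 were -0.82, -0.54 and -0.65 and still passed.

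Several further mRNAs fell in the main fit, but none named in this paragraph kept its call in every alternative, as given below. Mex3c, an RNA-binding ubiquitin ligase, fell 2.81-fold, with Control 1 at -1.85 against -1.54 to -1.52 on the other Control arrays. Map2, a microtubule-associated protein of neurons, fell 1.85-fold. B2m, the light chain of MHC class I, fell 1.76-fold, with Control 1 at 0.56 against 0.03 to 0.10. Cyp2e1, a cytochrome P450 that oxidises ethanol, fell 1.71-fold, Ppp2r2b, a regulatory subunit of protein phosphatase 2A, 1.63-fold, and the ribosomal protein gene Rpl13a 1.47-fold. The arylamine acetyltransferase gene Nat1 fell 1.46-fold and Enpp1, which makes pyrophosphate outside the cell, 1.44-fold, although the log2 change of Enpp1 was 0.019 with normexp. Besides Hsp90ab1, the mRNAs that rose were Dlg4, a scaffold of the postsynaptic density, by 1.80-fold, Pop7, a subunit of RNase P, by 1.48-fold, and the ubiquitin ligase gene Trim2 by 1.40-fold.

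Of 12 custom probes, which include many genes often used as references, 6 changed, 2 higher and 4 lower. B2m, Ldha, Rpl13a and Hsp90ab1 are the named ones among them. Actb, which encodes β-actin, had a log2 change of -0.19 (SE 0.16) that did not pass and was 0.13 with median centring. Pgk1, an enzyme of glycolysis, gave -0.38 (SE 0.24), Gusb -0.37 (SE 0.21; 0.031 with normexp), Rplp1 -0.38 (SE 0.34; 0.21 without Control replicates 3 and 4 and 0.33 against Control 1 alone) and Hprt1 0.48 (SE 0.32; adjusted p = 0.0435 by limma without Control replicates 3 and 4). Leaving out 1 array moved Pgk1 from -0.50 to -0.18, Gusb from -0.45 to -0.20, Rplp1 from -0.61 to -0.080 and Hprt1 from 0.23 to 0.70. Sdha, a subunit of mitochondrial complex II, gave 0.54 (SE 0.31), which did not pass. By limma it passed with median centring at 0.86 (adjusted p = 0.0424) and without Control replicate 4 at 0.80 (adjusted p = 0.0232). It also passed without Control replicates 3 and 4 at 1.11 (adjusted p = 0.00172), and was 1.12 against Control 1 alone. Without Control replicate 1 it was 0.35, without Control replicate 2 0.35 and with normexp 0.24, and it did not pass there.

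Among other named mRNAs that did not pass, the log2 change was 0.0078 (SE 0.35) for the inflammasome sensor Nlrp3, -0.13 (SE 0.22) for the growth factor Fgf2, 0.58 (SE 0.25) for the neurotrophic factor Gdnf and 0.25 (SE 0.29) for N-cadherin, Cdh2. The sign of Nlrp3 and Fgf2 turned in several alternatives. By limma, Gdnf passed with quantile normalization at 0.83 (adjusted p = 0.0126), with median centring at 0.90 (adjusted p = 0.00858) and without Control replicate 1 at 0.80 (adjusted p = 0.00708), but was -0.074 against Control 1 alone. Cdh2 passed by limma only without Control replicates 3 and 4, at 0.72 (adjusted p = 0.0291). It was 0.067 without Control replicate 2, 0.13 without Control replicate 1 and 0.091 with normexp. The array median of the mRNA panel was -1.37 ± 0.12 in Model and -1.04 ± 0.13 in Control (log2, SD, n = 4, exact permutation p = 0.0286, adjusted p = 0.0762). That of the tested circRNAs was -1.43 ± 0.08 and -1.11 ± 0.04 (log2, SD, n = 4), a similar gap. The median log2 change per probe was not similar, at -0.31 for the panel and -0.03 for the circRNAs. The direction of the panel followed the zero point: 14 probes were higher and 8 lower with median centring, and 6 and 22 with the percentile over probes detected on all arrays. With normexp, which changes more than the zero point, 3 were higher and 11 lower. With run as a random block, which cannot separate run from group, 14 mRNA probes changed, and without Control replicate 3 the count was 18. The run block ended the calls of Cyp2e1, Pop7, Enpp1, Rpl13a, Nat1, Trim2 and Ppp2r2b (limma adjusted p from 0.0547 to 0.183) through wider errors: their log2 changes were 0.949 to 1.07 times those without the block and their SE 1.31 to 1.37 times as large, as for Cyp2e1 at -0.77 (SE 0.22) without it and -0.83 (SE 0.29) with it. Of 19 alternatives run, Trim2 lost its call in 12, Nat1 and Ppp2r2b in 11 each, Enpp1 in 9, Rpl13a in 8, Pop7 in 5 and Cyp2e1 in 3; in 7, 5, 4, 6, 5, 4 and 1 of these, in that order, the change kept at least 90% of its size and the error was wider. Smaller changes ended the calls of B2m (-0.82, SE 0.21, to -0.50, SE 0.19) and 1 Ldha probe (-0.74, SE 0.17, to -0.42, SE 0.17) with median centring. Median centring also shrank Cyp2e1 (-0.77 to -0.45), Ppp2r2b (-0.71 to -0.39), Rpl13a (-0.55 to -0.23), Nat1 (-0.54 to -0.22) and Enpp1 (-0.52 to -0.20) and ended their calls. With normexp, smaller changes ended the calls of Dlg4 (0.85, SE 0.21, to 0.32, SE 0.11), Mex3c (-1.49, SE 0.23, to -0.23, SE 0.11) and Map2 (-0.89, SE 0.21, to -0.26, SE 0.11). The same held for Cyp2e1, Ppp2r2b, Nat1 and Trim2. Against Control 1 alone, Map2 was at -0.68.

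**Figure D3:**
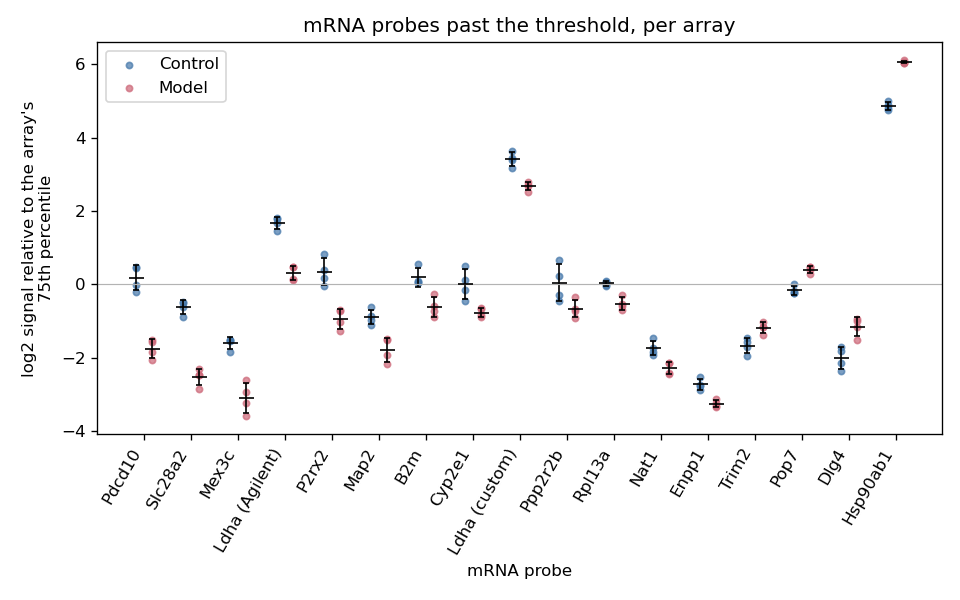
Log2 signal relative to the array's 75th percentile for the 17 mRNA probes with a gene symbol that changed, with points for the 4 Control and 4 Model arrays and bars for the mean ± SD. Hsp90ab1 is the brightest and is higher in Model (its change was -0.33 under quantile normalization), Pdcd10 and Slc28a2 are lower in Model, and Enpp1, lower here, had a log2 change of 0.019 with normexp.

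The circRNA named in the title of the series, circRNAs spliced from Rhoa and the 15 lists of host genes were not analysed here. The files give each circRNA probe by its array identifier alone, and no table used here pairs these identifiers with circRNA names or host genes. Of all genes on those lists, Sdha was the sole one with a tested mRNA probe.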

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

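The tests of the scanning run, of brightness and of linear RNA were chosen after the results they concern had been seen.

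In 5 of 78 sets of 4 arrays examined, 1 array lay far from the other 3, where chance gives about 1 in 20. The median log2 signal of the mRNA panel was -0.85 on Control 4 against -1.12 to -1.09 on the other Control arrays. The circRNA ASCRPR007908 was at 0.88 on Model 2 against -2.05 to -1.89 on the other Model arrays. Mex3c was at -1.85 on Control 1 against -1.54 to -1.52, Fgf2 at -1.09 on Control 1 against -1.95 to -1.84, and B2m at 0.56 on Control 1 against 0.03 to 0.10.

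Signal also appeared in custom probes without an accession, which the comparisons do not use. One such probe had a median processed signal of 15.6 intensity units on the Model arrays and at most 1.48 on any Control array, at least 3.74-fold higher in Model. Another had 7.88 in Model and at most 3.23 in Control, at least 1.94-fold higher. Both were well above background on all 4 Model arrays and on no Control array; the bounds set the Model mean against the dimmest signal called above background on each Control array. Of the probes of this kind that were well above background on all 8 arrays, 2 were lower in Model. Their log2 changes were -1.35 (SE 0.22) and -0.90 (SE 0.25), with limma adjusted p of 8.30e-04 and 0.0154. The others detected on all 8 arrays gave 0.046 (SE 0.44) and 0.096 (SE 0.40) and did not pass.

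The change of 6406 circRNAs was weighed against chance, brightness and the scanning run. Of 35 splits of the 8 arrays into 4 and 4, 1 gave as many changed circRNAs, the real one. The highest other split gave 0 in limma and, at an unadjusted p under 0.05, 2559 against 7390 in the real one. This argues against chance but cannot exclude it, since the smallest p that an exact permutation over these splits allows is 0.0286. Every other split mixes the groups, so a group difference widens its spread and lowers its count. Quantile normalization, which gives every array nearly the same brightness distribution, left 69.9% of the changed circRNAs changed in the same direction, which argues against brightness as the whole cause. Control 1 lay a median of 0.43 (log2) from the mean of Control 2 to 4, the other Control run, and this was 0.692 of the distance between the groups; pair by pair, Control 1 lay 0.29 to 0.63 from those arrays, which lay 0.25 to 0.53 from each other, and Control and Model arrays lay 0.62 to 0.81 apart. Scanning run and the effect of the model cannot be told apart, since no run held both groups, and either may contribute.

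The change of 28 mRNA probes was weighed against chance and against a different amount of linear RNA left after RNase R. Among the 35 splits, 1 gave as many changed mRNA probes, the real one. The highest other gave 0 in limma and, at an unadjusted p under 0.05, 13 against 33 in the real one. As for the circRNAs, this argues against chance but cannot exclude it. A uniform difference in leftover linear RNA would move the probes the same way, but 67.9% of the changed probes shared a direction, and log2 changes included -1.93 (SE 0.22) for Pdcd10 and 0.85 (SE 0.21) for Dlg4. The share cannot decide, since it moves with the zero point, from 22 of 28 lower with the percentile over probes detected on all arrays to 8 of 22 with median centring. With normexp 11 of 14 were lower. The gap between Pdcd10 and Dlg4 does not move with the zero point, but these 2 were named after their values were seen. With normexp they were at -0.82 and 0.32, and Dlg4 did not pass (limma adjusted p = 0.0667). Over the whole panel, changed probes went both ways with each zero point. In the main fit 9 were higher and 19 lower, with median centring 14 and 8, and with the percentile over detected probes 6 and 22. This argues against a uniform difference as the whole cause. A partial shift, unequal digestion of different mRNAs, the scanning run and the condition of the Model samples may each contribute, and these stay open.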

How the results depend on the processing

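Added after the data were seen were normexp on the median intensity, the comparison without Control replicates 3 and 4, that against Control 1 alone, the array signal from median intensity, and every alternative for the mRNA probes. Controls 3 and 4 were left out because they lay farthest from the Models, a choice made on the outcome itself; Control 1 alone is assumed to vary like the Model arrays.

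Against 6406 circRNAs changed, there were 3555 with normexp, 4042 with the scanning run as a random block (correlation 0.242) and 4144 against Control 1 alone. Against 3009 higher there were 4684 with median centring and 1912 with the run block. Against 3397 lower there were 2174, 1357, 2130 and 2122 with median centring, normexp, the run block and Control 1 alone. Against 28 mRNA probes there were 14 with normexp, 14 with the run block and 17 against Control 1 alone. Leaving out 1 array gave 5186 to 6966 circRNAs, 2419 to 3365 higher, 2767 to 3601 lower and 18 to 34 mRNA probes, the lowest without Control replicate 3. Without Control replicates 3 and 4, 6425 circRNAs and 24 mRNA probes changed. Except for fewer samples and the wider errors of the run block, the cause was not tested. The difference in array signal, -0.26, was -0.51 without Control replicate 2, -0.036 without Control replicate 4 and -0.58 with the median, and did not pass in any alternative run.

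The sign turned for Hsp90ab1 with quantile normalization (-0.33; adjusted p from 5.43e-05 to 0.415 over its alternatives), Actb with median centring (0.13), Gusb and Enpp1 with normexp (0.031 and 0.019) and Rplp1 without Control replicates 3 and 4 (0.21) and against Control 1 alone (0.33). It also turned for Gdnf against Control 1 alone (-0.074), for Fgf2 with quantile normalization (0.19), median centring (0.19) and normexp (0.019), and for Nlrp3 (0.0078) with the percentile over probes detected on all arrays (-0.12), the run block (-0.078), without Control replicates 3 and 4 (-0.34) and against Control 1 alone (-0.79). Leaving out 1 array gave -0.22 to 0.071 for Fgf2 and -0.25 to 0.27 for Nlrp3. The cause was not tested. Of 17 changed probes with a symbol, 4 passed in all 19 alternatives run: Pdcd10, Slc28a2, P2rx2 and 1 Ldha probe. With the run block, which cannot separate run from group, 10 passed.

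Replicate numbers showed no clear pairing of the samples (correlations of deviations 0.0607, -0.0386, 0.185 and -0.179). Among the Control arrays, only Control 3 matched its own number best. These correlations were set against no reference and cannot exclude pairing. With the replicate block 5942 circRNAs and 22 mRNA probes changed.

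Not run were normexp and array signal on the mean intensity, a column the files lack, and all alternatives for the circRNA of the title and the host gene lists. Dim probes limit what can be seen: 12113 of 14145 circRNA probes were well above background on all 8 arrays.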

Other observations

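All tests here were chosen after values of the circRNAs that fell most had been seen on each array, and those on the Control arrays and of neighbouring probe numbers after their own values had been seen; the question of joint variation was first put to the Model arrays, and it was moved to the Control arrays when the Model arrays gave no more than chance.

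The 100 circRNAs that fell most and the 100 that rose most were chosen for their change, so the gap between groups follows from the choice. For those that fell the median log2 signal was 0.34 on Control 1, 0.85 on Control 2, 1.09 on Control 3 and 1.06 on Control 4, against -2.70 to -2.01 on the Model arrays. The 100 that rose most had medians of 1.00 to 1.43 on the Control arrays and 4.01 to 4.41 on the Model arrays.

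Whether the 100 that fell most also vary together within a group was asked as a sign of a tissue component whose share differs between samples. Among the Model arrays their mean pairwise correlation was 0.0693, at the 47.9th percentile of 1000 sets of the same brightness, so they varied together no more than brightness gives. Among the Control arrays it was 0.213, above the 0.0882 of the highest matched set. The sets were matched on brightness but not on the size of change, so no cause is drawn from this correlation. Without Control 1 the correlation was 0.0155, below the 95th percentile of matched sets (0.0601), so Control 1 or its scanning run may account for it. A tissue component stays open, because Model samples with equal shares of it would not vary together.

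The 100 that rose most behaved otherwise. Their mean pairwise correlation was 0.259 among the Control arrays and 0.273 among Control 2 to 4, above all 1000 matched sets in each case, and at the 83.7th percentile among the Model arrays. Sets of the same brightness did not reach the Control values, with or without Control 1, but they were not matched on the size of change. No other explanation was tested for this set.

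A further hypothesis was that circRNA probes with consecutive numbers share a source and so change alike. The correlation of log2 changes over 13058 consecutive pairs was 0.0371, above the 0.0297 of the highest of 1000 random orders. It was 0.0257, 0.0145, 0.0349 and 0.0261 at distances of 2, 5, 10 and 50 numbers, with no steady drop, and probes are not independent replicates.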
